A study of Mus musculus with 32 samples.

How the data were processed

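Mouse brain, heart, kidney and liver, frozen or FFPE (fixed in 10% formalin), were assayed by methylated RNA immunoprecipitation with sequencing (MeRIP-Seq). Per the labels' protocols, RNA was sheared for 20 min by ultrasound in plates, pulled down with an antibody and turned into total RNA libraries with ribosomal RNA depletion. Per the submitters' processing notes, reads were processed with HISAT2, featureCounts and limma against mm10, with no versions, order or settings stated.

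The values used are log2 normalized counts in a table the authors deposited, with 27179 genes and 8 columns, 1 for each organ and preservation. From the values, each is log2 of CPM with 0.5 added to the count and a scaled library size per column. Each column turned back into gene counts, and 100.0% of the values came out whole within a tolerance of 0.001, relative to 10000 counts for larger counts. The scaled library size was 0.426 (FFPE liver) to 2.24 (FFPE brain) times the total gene count. How the authors chose these factors is not given in the sources used here. That the columns hold m6A libraries is taken from the name of the table, since the column names give only organ and preservation. A further 8 columns of a table named for another RNA mark matched no listed sample and were not used here. Of the gene identifiers, 25275 matched the reference annotation (GRCm38.p6, the assembly of mm10), which supplied coordinates, and 1275 had no symbol.

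The tests fixed before the data were examined were limma fits over 32 libraries with a mean per group. With 1 column per group that fit has no residual degrees of freedom, so an additive fit with a term for each organ and a term for preservation was used on the 8 libraries. It leaves 3 residual degrees of freedom, used by eBayes with a trend on the mean level. FFPE against frozen tissue then rests on 4 organs as blocks, and an organ against the mean of the other 3 rests on its frozen and FFPE library. These p-values measure how alike the organs, or the preservations, behaved, and not the spread between animals. Comparisons of m6A with input, and of whether an effect differs between organs, were not made, because input was not analysed here and each cell of the design holds 1 library. Differences within 1 organ are values with exact counting intervals and no test.

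Genes with a log2 value above 0 in at least 2 libraries were tested (14864 genes). Calls are at Benjamini-Hochberg adjusted p under 0.05. The 24 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01 and at an estimated one, for the 20 lists with 3 or more tested members. The rule for named genes, written for input and applied to m6A here, takes for each organ the 6 genes furthest above the other organs in frozen tissue that were called and higher in both preservations. For FFPE against frozen it takes up to 10 called genes each way with the same sign in 4 organs. Both need a mean log2 of at least 3 and pass over unnamed gene models and receptor segments, and list members may be named too. For kidney and liver, 1 gene that the rule takes is not reported here. Lists of Y-linked, sex-biased liver and chemosensory receptor genes were added after the data were seen.

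Alternatives listed in advance were quantile normalization, centring on medians, no filter, a stricter filter, library quality weights, no trend, leaving out each library, a 4-fold threshold for agreement and the estimated correlation. Alternatives chosen after seeing the data were scaling by total gene counts, scaling by counts outside the ribosomal genes, adding 2 counts, voom precision weights and leaving out both heart libraries.

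The fit was tested on simulated data with 14864 genes, with the changed genes drawn from those at a mean log2 of at least 3. All other genes had no change in the comparison. Noise was normal, independent between genes and drawn at the variance that the fit had already moderated. Real genes are not so simple, so the shares below do not show what the fit recovers in the real data. For FFPE against frozen, 85% of 100 genes changed by log2 1 and 100% of 100 genes changed by log2 2 were recovered, with 11 false calls. For liver against the other 3 organs, 73% and 99% were recovered, with 16 false calls. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.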

Results

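RNA that carries N6-methyladenosine (m6A), a methyl mark on adenosines of messenger and noncoding RNA, was pulled down with an antibody from mouse brain, heart, kidney and liver and sequenced. Each organ was represented by frozen tissue and by formalin-fixed, paraffin-embedded (FFPE) tissue, the form in which pathology archives keep specimens. The labels list 32 samples in 16 groups of 2 runs, 16 samples with the m6A antibody and 16 inputs. The table analysed here holds 1 column for each of the 8 m6A groups, so every organ and preservation is 1 library without replicates. Whether a column holds 1 run or both is not given in the sources used here. Input values were not analysed here, so a level below is the amount of a transcript in the pulled-down RNA. Abundance, methylation and other influences on the pulled-down RNA were not separated.

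Total gene counts recovered from the values ran from 9603050 in FFPE brain to 21523379 in frozen brain. Ribosomal transcripts (Rn45s, Rn18s, mt-Rnr1 and mt-Rnr2) took 50.4% of the counts in FFPE brain (95% Wilson interval 50.3 to 50.4%) and 79.7% in frozen heart (79.7 to 79.7%), with the other 6 libraries between. Outside these 4 genes, liver FFPE was the shallowest library with 3050241 counts and frozen brain the deepest with 8004550. The level that 3 counts give lay between log2 -3.29 in frozen brain and log2 -0.86 in FFPE liver, so genes below these levels were not measured reliably in those libraries. Intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Fewer genes had a count in FFPE than in frozen tissue of every organ. This need not mean fewer kinds of transcripts, since reads from genomic DNA could also give a count. When each library was thinned to 3050241 counts outside the ribosomal genes, 17126, 15474, 17198 and 14374 genes were expected with a count in FFPE brain, heart, kidney and liver. The frozen libraries had 19075, 21572, 21677 and 19798.

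The first comparison asked which transcripts set each organ apart in the pulled-down RNA. Brain libraries were rich in neuron and glia transcripts, heart libraries in cardiomyocyte marker transcripts, kidney libraries in nephron marker transcripts and liver libraries in hepatocyte marker transcripts. All members of the organ's own marker list were called higher in each organ: 15 of 15 neuron and 13 of 13 glia markers in brain, 16 of 16 cardiomyocyte markers in heart, 17 of 17 nephron markers in kidney and 20 of 20 hepatocyte markers in liver. The mean difference from the other 3 organs was log2 7.58 for neuron markers and 6.50 for glia markers. It was 9.01 for cardiomyocyte, 8.95 for nephron and 11.21 for hepatocyte markers. Over 3 counts were seen for only 2 of 20 hepatocyte markers in FFPE brain, 2 of 17 nephron markers in FFPE heart and 2 of 15 neuron markers in FFPE liver. The size of such differences is therefore set in part by the count added to 0. Against all other genes, camera with a preset correlation gave adjusted p = 8.22e-08 and 1.43e-06 for the neuron and glia lists, 2.46e-21 for cardiomyocyte, 4.55e-16 for nephron and 1.02e-17 for hepatocyte markers. With an estimated correlation none of these 5 lists passed (adjusted p = 0.321, 0.321, 0.107, 0.329 and 0.423). Every member of these lists was called, and the estimate rests on 3 residual degrees of freedom. A list that fails with an estimated correlation, here or below, may therefore still differ.

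**Figure D1:**
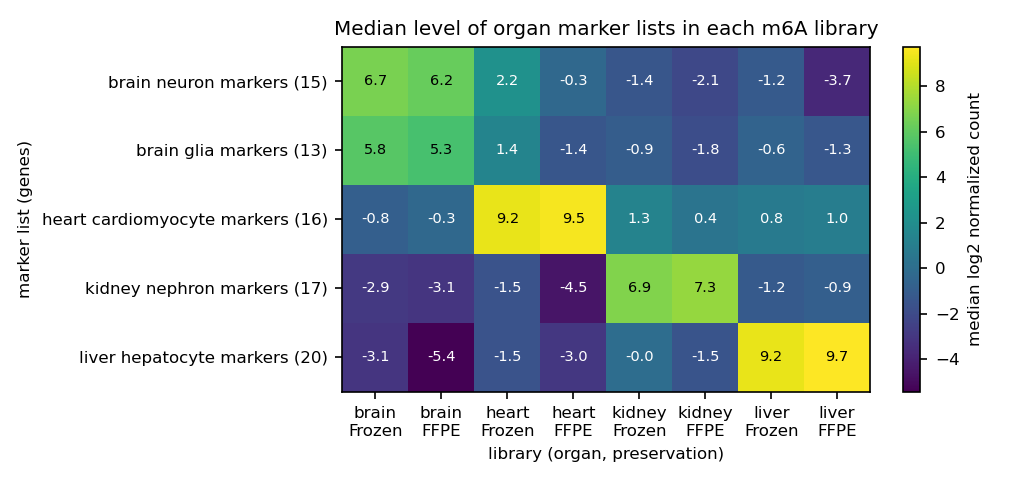
Median log2 normalized count of 5 organ marker lists (rows, number of genes in brackets) in the 8 m6A libraries (columns, organ and preservation); colour and printed number give the median. Each list is highest in the frozen and FFPE libraries of its own organ, and the neuron and glia markers lie higher in frozen heart (2.22 and 1.41) than in FFPE heart (-0.29 and -1.37).

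In brain, Mbp, the myelin basic protein gene on chromosome 18 (82475091 to 82585637, GRCm38.p6), was higher by log2 7.16 ± 0.40 (SE; adjusted p = 4.09e-06), with 7.35 in frozen and 6.97 in FFPE tissue. The long noncoding RNA Meg3 differed by 7.85 ± 0.46, the microtubule-associated genes Map1a and Map1b by 7.11 ± 0.47 and 6.30 ± 0.29, the neuronal kinesin gene Kif5a by 7.21 ± 0.60 and the calcium pump gene Atp2b2 by 6.45 ± 0.64. Nuclear-encoded oxidative phosphorylation genes were lower in brain, with 69 of 75 called lower (mean log2 -1.19; camera adjusted p = 2.28e-14, and adjusted p = 0.505 with an estimated correlation). Endothelial and fibroblast markers were lower as well, with 11 of 12 and 9 of 11 called lower and 1 fibroblast marker called higher (mean log2 -2.06 and -2.44; camera adjusted p = 1.80e-05 and 9.01e-05, or 0.481 and 0.321 as adjusted p with an estimated correlation).

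In heart, Myh6, the alpha heavy chain of cardiac myosin on chromosome 14 (54941921 to 54968017), stood log2 9.78 ± 0.36 above the other organs (SE; adjusted p = 1.13e-06). Myoglobin (Mb, 9.35 ± 0.35), troponin T (Tnnt2, 9.33 ± 0.32), titin (Ttn, 9.14 ± 0.21), cardiac actin (Actc1, 8.79 ± 0.26) and myosin-binding protein C (Mybpc3, 8.54 ± 0.32) followed. Energy transcripts were higher in heart than in the mean of the other 3 organs: 67 of 75 oxidative phosphorylation genes were called higher and 2 lower (mean log2 1.31; camera adjusted p = 7.12e-25), and 12 of 15 mitochondrially encoded genes were called higher (mean 1.69; adjusted p = 2.04e-05). With an estimated correlation these gave adjusted p = 0.397 and 0.588. The mitochondrially encoded median was nevertheless higher in FFPE liver (10.87) than in FFPE heart (10.62). Endothelial markers (12 of 12 called higher, mean 2.25) and fibroblast markers (10 of 11 higher and 1 lower, mean 2.33) were also higher in heart, with camera adjusted p = 5.91e-10 and 4.26e-07 and, with an estimated correlation, adjusted p = 0.397 and 0.320.

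In kidney, Lrp2, which encodes the proximal tubule uptake receptor megalin (chromosome 2, 69424335 to 69586029), differed by log2 9.25 ± 0.41 (SE; adjusted p = 8.81e-06). The growth factor gene Egf (8.01 ± 0.32), the plasma peroxidase gene Gpx3 (7.84 ± 0.26) and the fatty acid transporter gene Slc27a2 (6.76 ± 0.21) were also higher. Pck1, the gluconeogenic enzyme PEPCK, was called in both organs that make glucose, by 7.56 ± 0.66 in kidney and 9.04 ± 0.66 in liver. In liver, albumin (Alb, chromosome 5, 90460870 to 90476602) differed by 13.35 ± 0.58 (adjusted p = 1.33e-06), apolipoprotein B (Apob) by 11.06 ± 0.46, the cytochrome P450 gene Cyp2e1 by 10.05 ± 0.23 and complement C3 by 9.30 ± 0.23. The m6A writer, eraser and reader list did not pass in any organ. Of 19 genes tested, 6 were called higher and 4 lower in brain, and camera adjusted p was 0.653 in brain, 0.819 in heart, 0.946 in kidney and 0.873 in liver.

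Over 14864 genes, limma called 4491 genes higher and 3928 lower in brain, 2370 and 2691 in heart, 2399 and 2011 in kidney, and 2981 and 4042 in liver (adjusted p under 0.05). The fit had 3 residual degrees of freedom, and frozen and FFPE tissue served as the 2 observations of each organ. The balance of directions depended on how libraries were scaled. With quantile normalization 3952 genes were higher and 4983 lower in brain and 3075 and 2575 in heart, the opposite balance. With libraries centred on their medians the calls were 3792 and 4866 in brain, 2819 and 2160 in heart, 2233 and 2236 in kidney and 3567 and 3448 in liver. Scaled by total gene counts, 8234 genes were called higher and 1558 lower in brain, 1107 and 3508 in heart, 2822 and 1013 in kidney, and 1143 and 8628 in liver. Scaled by counts outside the ribosomal genes, the calls were 6502 and 2815 in brain, 1994 and 3262 in heart, 4326 and 1247 in kidney, and 1630 and 8007 in liver.

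The second comparison asked how far FFPE tissue gave the same organ profile as frozen tissue. Organ identity dominated: the first 3 principal components, with 52.9, 20.3 and 17.2% of the variance, separated the organs. The fourth, with 4.71%, parted FFPE from frozen tissue in every organ, with scores of -29.4, -43.2, -32.2 and -57.7 in FFPE brain, heart, kidney and liver and 8.61, 64.2, 33.2 and 56.5 in the frozen libraries. Across the 14864 genes, which are not independent replicates, levels in frozen and FFPE tissue of 1 organ correlated with Pearson r of 0.957 in brain, 0.902 in heart, 0.940 in kidney and 0.909 in liver. Spearman's rho was 0.966, 0.938, 0.967 and 0.935. Libraries of different organs of the same preservation reached at most r = 0.677. Of the genes at least 2-fold above the other organs in frozen tissue, 3519 of 4125 were also at least 2-fold higher in FFPE brain (1113 expected for independent lists), 1874 of 2472 in heart (445 expected), 2069 of 2508 in kidney (470 expected) and 2080 of 2611 in liver (513 expected). Pooled over organs, 9542 of 11716 were shared, or 81.4% (exact binomial interval 80.7 to 82.1%). The interval treats genes as independent, which they are not. The filter on low values can raise this share. A gene confined to 1 organ passes it mainly when both libraries of that organ lie above the cutoff. With no filter, 15269 of 25315 were shared, or 60.3%, so the 81.4% holds for the filtered genes only. Heart had the lowest agreement, with 171 genes at least 2-fold higher in frozen and at least 2-fold lower in FFPE heart, against 6 in brain, 11 in kidney and 61 in liver. These shares have no test, since each profile is 1 library.

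The frozen heart library carried brain transcripts. Neuron markers had a median of log2 2.22 in frozen heart and -0.29 in FFPE heart, and glia markers 1.41 and -1.37, while frozen kidney (-1.37 and -0.93) and frozen liver (-1.16 and -0.63) lay lower. Snap25, a synaptic vesicle fusion gene, was at 3.15 in frozen heart, 0.41 in FFPE heart and 8.45 in frozen brain. Slc1a2, the astrocyte glutamate transporter gene, was at 5.12, 1.61 and 9.53, although liver also expressed it at 6.13.

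The third comparison asked which transcripts differed between FFPE and frozen tissue in the same way in all organs. The long noncoding RNA Xist, which coats the inactive X chromosome of female cells, was the 1 gene called over 14864 genes. It stood log2 9.15 ± 0.41 (SE; limma adjusted p = 1.01e-04) higher in FFPE tissue, with 10.20 in brain, 7.91 in heart, 8.15 in kidney and 10.33 in liver. Xist (chromosome X, 103460373 to 103483233) had 4050, 2693, 6685 and 4477 counts in FFPE brain, heart, kidney and liver and 5, 12, 26 and 5 in the frozen libraries. Y-linked genes, which only male cells carry, were measured in all 8 libraries and were lower in FFPE in 16 of 16 pairs of gene and organ. The counting interval lay below 0 in 13 of them. The largest of these differences was in Ddx3y, an RNA helicase gene (chromosome Y, 1260715 to 1286628), at log2 -1.61 ± 0.20 (adjusted p = 0.0531, or 0.0307 with the stricter filter).

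**Figure D2:**
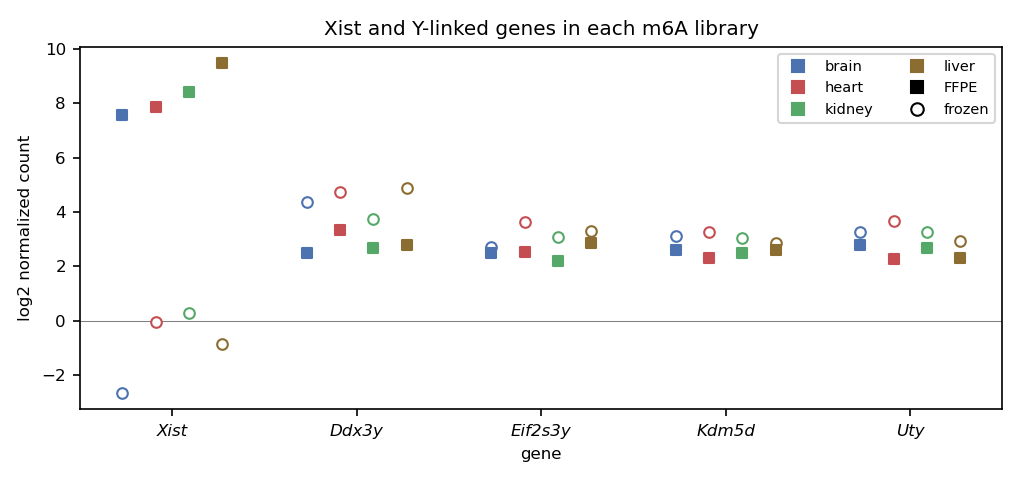
Log2 normalized count (y axis) of Xist and 4 Y-linked genes (x axis) in the 8 m6A libraries; filled squares are FFPE, open circles are frozen, and colour gives the organ. Xist lies at 7.56 to 9.47 in FFPE and at -2.64 to 0.28 in frozen tissue, and each Y-linked gene is lower in FFPE than in frozen tissue of the same organ.

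Small noncoding RNAs were higher in FFPE among the members that could be tested. All 34 tested small nucleolar, Cajal body and related RNA genes were higher in FFPE (mean log2 2.99, median 2.92; camera adjusted p = 1.13e-26, and adjusted p = 0.539 with an estimated correlation). Of these, 29 passed when adjusted over the list alone and 0 over all genes. Of 142 members only 34 were tested, and 25 of these passed the filter on low values only with the help of FFPE libraries, so the change itself partly chose them. The 9 that passed in frozen libraries alone, counted after the result was seen, were all higher (mean 1.69, median 1.45). The list mean was 1.67 with no filter (adjusted p = 1.34e-31) and 1.80 with the stricter filter (adjusted p = 0.00119). Organ medians of the 34 were 1.85 in brain, 1.04 in heart, 4.15 in kidney and 4.36 in liver. Abundant members included Rmrp, the RNA of a mitochondrial and nucleolar RNA-processing ribonuclease (chromosome 4, 43492785 to 43493059), at log2 2.84 ± 0.36 (SE; adjusted p = 0.0531), Rpph1, the RNA of ribonuclease P, at 1.45 ± 0.27 (adjusted p = 0.0733) and Rn7sk at 1.12 ± 0.17 (adjusted p = 0.0572). Many small nucleolar RNAs lie inside introns of other genes, so reads of the host could have been counted for either, and the list median in the frozen libraries was between log2 -2.37 and -0.31, where counts are few.

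Nuclear-encoded genes of oxidative phosphorylation were lower in FFPE as a list. Of 75 nuclear-encoded oxidative phosphorylation genes, 70 were lower in FFPE (mean log2 -0.54; camera adjusted p = 4.87e-20, and adjusted p = 0.539 with an estimated correlation). Over the list alone 48 passed, and over all genes 0. Among them were Atp5j2 (log2 -1.09 ± 0.16 SE, adjusted p = 0.0572), Ndufa2 (-1.07 ± 0.20, adjusted p = 0.0757) and Ndufa13 (-1.03 ± 0.16, adjusted p = 0.0572), each lower in 4 of 4 organs. The list median was -1.24 in brain, -0.25 in heart, -0.30 in kidney and -0.48 in liver, and without FFPE or frozen brain the mean was -0.33 (adjusted p = 6.77e-13 and 1.03e-12). Cytosolic ribosomal protein genes were lower in 68 of 80 cases (mean -0.31; camera adjusted p = 1.09e-06, and adjusted p = 0.635 with an estimated correlation), and 0 passed when adjusted over the list alone. The median was -0.97 in brain against -0.14 in heart, -0.25 in kidney and 0.04 in liver. Without FFPE or frozen brain the ribosomal list gave mean log2 -0.09 (adjusted p = 0.0468 and 0.0533). Mitochondrially encoded genes did not pass with all libraries (mean log2 0.16, camera adjusted p = 0.231), with medians of -0.78 in brain, -0.38 in heart, 0.75 in kidney and 1.18 in liver. Their mean was 0.51 with FFPE or frozen brain left out, 0.39 with FFPE heart left out and -0.21 with FFPE or frozen liver left out.

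**Figure D3:**
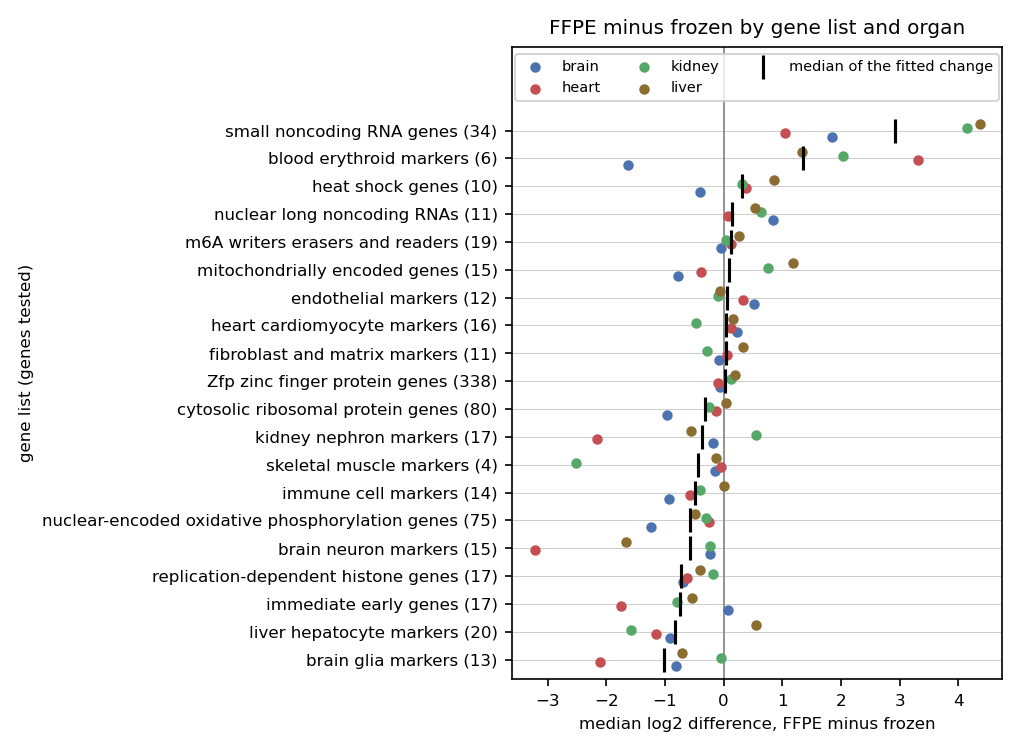
Median log2 difference of FFPE minus frozen tissue (x axis) for the 20 gene lists with at least 3 genes tested (y axis, genes tested in brackets); coloured dots are the 4 organs and the black bar is the median of the fitted change. Small noncoding RNA genes lie above 0 in all 4 organs (1.04 to 4.36) and oxidative phosphorylation genes below 0 in all 4 (-1.24 to -0.25).

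Immediate early genes, which switch on within minutes of a stimulus, were lower in FFPE in 15 of 17 cases (mean log2 -0.83; camera adjusted p = 5.35e-04, and adjusted p = 0.539 with an estimated correlation). The organ medians were -1.75 in heart, -0.79 in kidney, -0.54 in liver and 0.07 in brain. Fos was at log2 -2.38 ± 0.67 (SE; adjusted p = 0.149) and Junb at -1.28 ± 0.33 (adjusted p = 0.138). Histone genes were lower in 13 of 17 cases (mean -0.42; camera adjusted p = 0.0159, and adjusted p = 0.539 with an estimated correlation), among them the linker histone genes H1f2 (-1.10 ± 0.22) and H1f4 (-1.07 ± 0.14). Only 17 of the 63 histone genes listed were tested. The list did not pass with no filter (adjusted p = 0.274), quantile normalization (0.0526) or scaling by total gene counts (0.0768). Nor did it pass without both heart libraries (camera adjusted p = 0.0660). The list mean was -0.32 there and with either heart library left out, and -0.29 with frozen brain left out.

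Nuclear long noncoding RNAs as a list gave camera adjusted p = 0.0111 with a mean of log2 0.86 and a median of 0.15 (adjusted p = 0.539 with an estimated correlation). Xist alone carried the mean: the other 10 members had a median of -0.040. Besides Xist, the higher members included Neat1 (0.68 ± 0.12, SE), Malat1 (0.91 ± 0.36) and Kcnq1ot1 (1.03 ± 0.18), and 5 of 11 were lower. Without FFPE or frozen brain the list did not pass (adjusted p = 0.0811 and 0.0917). Heat shock genes had a mean of 0.53 with 6 of 10 higher (camera adjusted p = 0.0412, and adjusted p = 0.635 with an estimated correlation), and 10 of 20 other settings changed this call. Adjusted p was 0.970 with the stricter filter, 0.369 with quantile normalization, 0.112 with quality weights and 0.203 with voom weights. The heat shock mean was 0.42 with FFPE or frozen heart left out and 0.33 with FFPE or frozen liver left out. Settings that leave out either library of 1 organ share 1 estimate, so the 20 settings are not all separate checks. The m6A writer, eraser and reader genes had a mean of 0.12 with 14 of 19 higher (camera adjusted p = 0.0412, and adjusted p = 0.556 with an estimated correlation). This call was lost in 14 of 20 other settings, among them quantile normalization (adjusted p = 0.563), centring on medians (0.0801), quality weights (0.112) and 2 counts added (0.0743). The list mean was 0.11 with FFPE or frozen heart left out and 0.07 with FFPE or frozen liver left out. The mean turned to -0.03 (adjusted p = 0.317) when libraries were scaled by counts outside the ribosomal genes.

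Markers of blood and of the organs themselves also differed between preservations. Erythroid markers were higher in FFPE (mean log2 1.25, 6 of 6 higher; camera adjusted p = 0.0111, and adjusted p = 0.556 with an estimated correlation). Their medians were 3.32 in heart, 2.03 in kidney, 1.34 in liver and -1.63 in brain. Over the other settings the list mean ran from 0.58, without both heart libraries, to 2.13. The alpha globin gene Hba-a1 differed by 3.14 in heart and -0.98 in brain. Its neighbour Hba-a2 is nearly identical, so reads could have been split between them. Immune markers were lower in 12 of 14 cases (mean -0.62; camera adjusted p = 0.0111, and adjusted p = 0.539 with an estimated correlation), and the list did not pass with no filter (adjusted p = 0.0664).

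Neuron, glia and hepatocyte markers were lower in FFPE as lists (mean log2 -1.08, -1.11 and -0.86; camera adjusted p = 0.00675, 0.00257 and 5.01e-04). With an estimated correlation these gave adjusted p = 0.543, 0.539 and 0.539. In brain itself the medians were -0.23 for neuron and -0.81 for glia markers, against -3.22 and -2.11 in heart. Hepatocyte markers had a median of 0.55 in liver and -1.58 in kidney, and their list gave adjusted p = 0.398 with quantile normalization and a mean of 0.29 (adjusted p = 0.328) with voom weights. Only 2 of 20 hepatocyte markers in FFPE brain, 5 of 20 in FFPE heart and 2 of 15 neuron markers in FFPE liver had over 3 counts. Those differences are set in large part by the count added to 0. Without both heart libraries the neuron, glia, immune and erythroid lists did not pass (adjusted p = 0.157, 0.160, 0.101 and 0.207). Leaving out FFPE heart or frozen heart alone gave these lists the same means as leaving out both, so these settings are not separate checks. The means were log2 -0.55 for neuron, -0.62 for glia and 0.58 for erythroid markers. Immune markers had a mean of -0.47 without frozen heart and without both. The neuron list also failed with quantile normalization (adjusted p = 0.181) and quality weights (adjusted p = 0.0587), and the glia list with the stricter filter (adjusted p = 0.298). Endothelial, fibroblast, cardiomyocyte, nephron, skeletal muscle and zinc finger lists did not pass over the 14864 genes (camera adjusted p = 0.0762, 0.870, 0.870, 0.397, 0.303 and 0.189). The endothelial list passed with no filter (mean log2 0.14, camera adjusted p = 0.0290). Its mean was 0.25 with FFPE or frozen kidney left out and 0.24 with FFPE or frozen liver left out. The zinc finger list passed with the stricter filter (0.22, adjusted p = 0.00351) and without FFPE heart (0.01, 0.0471). The adipocyte, pancreas, adrenal and lung lists had 1 tested member each.

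With an estimated correlation between genes, 0 of the 20 lists passed in this comparison. The organs' own marker lists also failed with it in the organ comparisons, although every member was called. Failing there is thus weak evidence against a list. At an unadjusted p under 0.05, limma gave 1304 genes higher and 1465 lower in FFPE, of 14864. Adjusted p was under 0.1 for 238 genes, and 4072 genes changed in the same direction in all 4 organs. With 3 residual degrees of freedom, a count of 1 at adjusted p under 0.05 does not show that the other genes were unchanged. With the stricter filter (mean log2 of at least 3, 4466 genes), 124 genes were called higher and 56 lower. Over the 14864 genes, where 1 gene was higher and 0 lower with the deposited scaling, 12 were higher and 16 lower with quantile normalization, 31 and 178 when scaled by total gene counts, and 11 and 32 when scaled by counts outside the ribosomal genes.

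Further genes were chosen by the same rule on that stricter filter, after the count of 1 was seen. Over all 14864 genes their adjusted p lay between 0.0531 and 0.0981, Xist apart. Higher in FFPE in 4 of 4 organs were Xist, Rmrp and Rpph1 and also Rny3, a small RNA bound by the Ro protein (log2 2.88 ± 0.62 SE, adjusted p = 0.0486 with this filter) and Syvn1, an endoplasmic reticulum ubiquitin ligase gene (1.67 ± 0.26, adjusted p = 0.0334). So were Slc29a1, a nucleoside transporter gene (1.33 ± 0.27), Slc25a37, the mitochondrial iron importer of red cells (1.30 ± 0.27), Ypel2 (1.15 ± 0.24), Arhgef10l (1.15 ± 0.25) and Dusp11, an RNA phosphatase gene (1.13 ± 0.13). Lower in 4 of 4 organs were Ddx3y, H1f2 and Atp5j2, the peroxisomal fatty acid oxidation gene Ehhadh (-1.53 ± 0.19, adjusted p = 0.0307) and the retinol enzyme gene Retsat (-1.50 ± 0.28). Also lower in 4 of 4 were Hsd11b1, which activates glucocorticoids (-1.28 ± 0.25), Fkbp5, a glucocorticoid-induced co-chaperone gene (-1.24 ± 0.19), the retinal dehydrogenase gene Aldh1a1 (-1.18 ± 0.22), S100a10 (-1.12 ± 0.20) and Cpt2, which imports fatty acids into mitochondria (-1.09 ± 0.18). FFPE minus frozen changes of different organs correlated weakly across genes, with Pearson r from 0.117 between brain and liver to 0.327 between heart and kidney.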

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

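The FFPE minus frozen medians of 4 gene lists lay on opposite sides of 0 in different organs. The margin of log2 0.5 each way was chosen after the data were seen. These differences between organs were not tested, since each organ has 1 library of each preservation. Erythroid markers spanned log2 4.94, from -1.63 in brain to 3.32 in heart. Nephron markers spanned 2.71, from -2.16 in heart to 0.55 in kidney. Over 3 counts were seen for 11 of 17 in frozen heart (median log2 -1.53) and for only 2 of 17 in FFPE heart. Fewer of these markers were thus seen in FFPE heart, but the size of the heart value is set by the count added to 0. Hepatocyte markers spanned 2.13, from -1.58 in kidney, where 13 of 20 had over 3 counts in FFPE, to 0.55 in liver. Mitochondrially encoded genes spanned 1.96, from -0.78 in brain to 1.18 in liver.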

How the results depend on the processing

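The alternatives that rescale libraries by recovered counts, add 2 counts, use voom weights or leave out both heart libraries were chosen after seeing the data.

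For FFPE against frozen tissue, 1 gene was called. The count was 28 with quantile normalization, 10 with no filter, 180 with the stricter filter, 174 with library quality weights, 0 with no trend, 209 when scaled by total gene counts, 43 when scaled by counts outside the ribosomal genes, 105 with 2 counts added, 447 with voom weights and 4 without both heart libraries. Leaving out 1 library gave 1 to 5 genes, the latter without frozen heart. Xist was among the genes called under each of these settings except no trend. The median change over all genes was log2 -0.07, and moved to -0.18 and -0.22 under the scalings by total counts and by counts outside the ribosomal genes. Fewer genes entered the stricter filter; the cause of the other differences was not tested.

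Organ counts stayed within 1.5 times under most settings. Without a filter, 13329 genes were called in brain against 8419. With the stricter filter the counts were 2667 in brain, 2079 in heart, 1443 in kidney and 2365 in liver, as fewer genes entered. Leaving out 1 library gave 4993 to 8430 calls in brain, 2350 to 5333 in heart, 1435 to 4604 in kidney and 4768 to 6770 in liver, the lowest when the FFPE library of that organ was left out. Its lone library is then assumed to vary like the others.

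The pooled share of frozen organ genes shared with FFPE was 81.4%; it was 88.5% at the 4-fold threshold, 79.0% with quantile normalization, 60.3% with no filter, 80.5% with the stricter filter, 75.4% and 82.2% when scaled by total counts and by counts outside the ribosomal genes, 82.5% with 2 counts added and 83.6% without both heart libraries.

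For named genes under alternatives, 731 values kept their direction and side of the threshold, 98 passed it newly and 1 fell short. No organ gene changed sides. The 98 all came from FFPE against frozen genes that were picked because they passed with the stricter filter but not over all genes. New passes were thus partly built in and are no support. The 1 that fell short was Xist, with no trend. For gene lists, 319 values kept their side of the threshold, 60 lost their call, 10 gained it and 2 turned direction in camera from a list that passed. Heat shock genes gave camera adjusted p = 0.970 with the stricter filter (mean log2 0.10, placed lower than other genes by camera). Hepatocyte markers gave a mean of 0.29 with voom weights. Turns between settings that both failed were counted as kept. The mean of nephron markers, for one, went from -0.31 to 0.34 with quantile normalization. These values are not all separate checks, since leaving out either library of an organ gives 1 estimate.

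No paired analysis was possible because the columns carry no run number to pair runs by, while the organ term does pair the 2 libraries of each organ. The fits with only the groups in a comparison and with the other table were not run, nor was the pseudocount of 0.1 listed for linear values, since the values are log2. Depth limits genes near the level of 3 counts, most in FFPE liver. With 8 ways to part the 2 libraries of every organ, the splits were too few for a share under 0.05: 1 split, the real one, reached as many genes, with 1 gene called (highest other 0) and 180 with the stricter filter (highest other 0).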

Other observations

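The tests here were chosen after the results were seen, except those on receptor genes that measure the share of reads in 10 genes and the evenness of reads. Male-biased liver transcripts were far higher in FFPE than in frozen liver. All 8 measured members were higher, with a median of log2 3.73. None of 10000 random lists matched on level reached it. The list was added after the data were seen and its genes are regulated together, so this describes these 2 libraries only and is no independent support. Elovl3, a fatty acid elongase gene, had 860 counts in FFPE and 107 in frozen liver (log2 3.66, counting interval 3.38 to 3.97), the urinary protein gene Mup20 933 and 106 (3.80, 3.51 to 4.11), the bile acid enzyme gene Cyp7b1 251 and 18 (4.43, 3.78 to 5.24) and the transporter gene Slco1a1 626 and 10 (6.56, 5.74 to 7.70). Hsd3b5 had 122 counts in FFPE and 0 in frozen liver. Female-biased liver genes showed no such shift (median 0.06, 6 of 10 higher, percentile 46.4 of random lists), and Cyp2b9 had 855 and 2016 counts. Cidec, a lipid droplet gene picked after its values were seen, had 1 count in FFPE and 399 in frozen liver. These are differences between 2 libraries, with no replicate check.

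Xist was higher and Y-linked genes were lower in FFPE tissue. A general rise of nuclear long noncoding RNAs is argued against, since the other 10 had a median change of log2 -0.040 and a highest of 1.03, in Kcnq1ot1. The authors' scaling is argued against too: Xist was at least log2 8.995 higher under 4 other scalings, and the mean of the Y-linked genes stayed lower (-0.90 as deposited, -1.01 and -1.05 under 2 rescalings). RNA of female animals in the FFPE libraries only may account for it but stays open: that 16 of 16 pairs of Y-linked gene and organ were lower is the pattern itself, and X-linked homologs went both ways (Kdm6a 0.70 ± 0.18 and Kdm5c 0.59 ± 0.13, SE, higher in 4 of 4 organs, Ddx3x -0.08 ± 0.12 and Eif2s3x -0.49 ± 0.17). The higher male-biased transcripts in FFPE liver are not accounted for by it, and the sex of the animals is not among the labels used here.

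Brain transcripts appeared in frozen heart. Among 146 genes chosen on FFPE libraries alone (log2 of at least 5 in brain and at least 6 above the other organs), the median in frozen heart lay at log2 -4.35 relative to frozen brain, a ratio of 4.91%, and 84.9% of the genes lay within 2-fold of that ratio. Brain RNA mixed into the frozen heart library may account for this. The same share was 69.9% in FFPE heart, 58.9 and 57.5% in FFPE and frozen kidney and 67.1 and 61.6% in FFPE and frozen liver. These shares cannot be set against that of frozen heart, where the genes had a median of 41.5 counts, against 0 to 8 in these libraries. The genes were also chosen to be low in the FFPE libraries outside brain. Whether the share sets frozen heart apart is thus left open. Nerve fibres and ganglia of the heart stay open. Glia markers of the brain lay only log2 -0.57 from neuron markers (medians -4.92 and -4.35). This would count against nerves only if nerves of the heart carried few glia transcripts, which was not checked. An even spread of brain reads over frozen libraries is argued against, since the nearer of kidney and liver was at log2 -2.61 relative to heart. Whether mixing arose at dissection, in the plate or in sequencing was not tested.

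Chemosensory receptor genes, which are silent in most organs outside the nose, mouth and vomeronasal organ, had reads in frozen libraries. Of 1531 such genes, 577, 886, 990 and 698 had a count in frozen brain, heart, kidney and liver, against 30, 15, 110 and 10 in FFPE. Depth is argued against, since at equal depth the lowest frozen library was expected to hold 297 of them and the highest FFPE library 80.7. A few genes or paralogs are argued against, since 10 genes took at most 12.7% of receptor reads in a frozen library. Reads from genomic DNA in frozen tissue could account for it: at least 74.2% of the genes expected for even reads had a count, but broad low transcription would look alike, so these cannot be told apart.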
